A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

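RNA polymerase I (Pol I) occupancy of the yeast ribosomal DNA (rDNA) was measured by native elongating transcript sequencing (NET-seq) in 6 libraries of Saccharomyces cerevisiae, 2 from wild-type (WT) cells, 2 from cells lacking CDC73 and 2 from cells lacking PAF1. Per the labels' protocols, cells were collected on filters and lysed frozen, Pol I was immunoprecipitated, and a linker that carried a unique molecular identifier was joined to the 3' ends of the RNA before cDNA synthesis, circularisation and amplification. The submitters' processing notes name bcl2fastq 2.20.00, FastQC 0.11.7, cutadapt 3.4, STAR 2.7.1a, SAMtools 1.6, bedtools 2.28.0, R 4.3.2 and the genome build R64. How the molecular identifiers were used, which end of a read gave its position, and how reads that match several rDNA repeats were placed are not given in the sources used here.

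The authors deposited 3 tables, 1 for each pair of genotypes, with 6858 positions each. Per the file headers, each row holds a coordinate of chromosome XII, the position from the start of the transcribed rDNA, the base and the region. The positions cover chromosome XII from 467569 down to 460712 on the minus strand, and the 7 regions had the same ends as the rDNA genes of the reference table of that build. The deposited signal at a position is the number of reads scaled so that positions 1 to 6739 sum to 1000000 in each library, as the values show. The last 119 positions, from 6740 on, lie outside that sum but on the same scale. Dividing by the smallest value of a library gave whole reads, within 0.1 read, at 100% of positions in both WT libraries and at 99.9% and 100.0% in the cdc73 deletion libraries. In the deletion libraries 21 values were a whole number plus 0.5, and their origin is unknown. The WT libraries then held 480708 and 226202 reads, the cdc73 deletion libraries 18428847.5 and 14965806.5, and the paf1 deletion libraries 29671814 and 14203939.5 if the smallest value there is 1 read. The same division gave whole reads at 99.9% and 100.0% of positions in the paf1 deletion libraries too. Their columns were judged to hold too few low values, so no count test was run on them. The authors' deposited table of each pair also gives means, a ratio, a difference and a p-value. The deposited p-value equals Welch's test on the linear values and is not adjusted, and the deposited ratio is set to 100 where the first mean is 0.

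The planned test depended on the unit. Because the values were scaled and not counts, the planned limma test was used in place of the planned count test. Positions with a value above 0 in at least 2 of the 4 libraries of a comparison were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(value + pseudocount), without a block. The pseudocount was 0.5 times the median of the values above 0, which gave 48.1 for the paf1 deletion against WT, 44.3 for the cdc73 deletion against WT and 47.4 for the paf1 deletion against the cdc73 deletion. Fold changes of positions are on this log2(value + pseudocount) scale, which understates the change of low positions. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Shares of occupancy in 69 windows of 100 nt were tested by limma without trend. For the paf1 deletion against WT that fit took one spread for all windows. Regions were tested as lists with camera at a preset correlation of 0.01 and at an estimated one.

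Shares are of all 6858 positions and add up to a fixed total in each library, so a lower share of one region raises those of others. The scaled signal of single positions is relative in the same way. Total Pol I occupancy was not measured. Per library, the share of each region, the mean position weighted by occupancy, the Gini coefficient, the share in the top 1% of positions (69 positions), the share within 2 nt of the mature 18S, 5.8S and 25S 3' ends, and the relative occupancy by base were compared with exact two-sided permutation tests. With 2 libraries against 2 the smallest p such a test can give is 0.333, so no such comparison can pass 0.05. A pause site was a position above the mean + 3 SD of the 101-nt window around it, itself left out, in both libraries of a genotype. Spearman and Pearson correlations were across positions, which are not independent replicates. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9. The positions named are the 10 with the largest rise and the 10 with the largest fall in each comparison among those with adjusted p under 0.05, a mean at or above the median of tested positions and groups that do not overlap. Every region and the 5 windows with the largest change in each direction are also named. These rules, the tests and most alternatives were fixed before the data were examined. Alternatives added later were edgeR 4.0.16 on the recovered reads of WT and the cdc73 deletion, thinning of all libraries to 226202 reads, array weights, windows or bases of the spacers alone, correlations within regions and a crossed pairing.

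The tests were run on simulated data. In 200 changed positions, limma recovered 100%, 99% and 100% of 2-fold changes for the paf1 deletion against WT, the cdc73 deletion against WT and the paf1 deletion against the cdc73 deletion, and false calls were 1.96%, 1.49% and 2.44% of all calls. The median fitted log2 change of the 2-fold positions was 1.008, 0.994 and 1.005. It was thus free of the understatement that the pseudocount brings at low positions, so this recovery cannot be taken to hold there. On simulated windows, 10 of 10 changed by 1.5-fold were recovered in each comparison. The rule for pause sites found 40 of 40 planted sites at each genotype's depth, but on simulated profiles without planted sites it still named 44, 55 and 63 positions at the depth of WT, the cdc73 deletion and the paf1 deletion. The labels do not say that the 2 libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Their reads differed by more than sampling noise, with a chi-square per degree of freedom of 1.79 in WT, 29.4 in the cdc73 deletion and 56.1 in the paf1 deletion. This ratio grows with depth, so it does not rank the genotypes by how well their libraries agree. The tables cover the rDNA alone, so the deleted genes could not be checked in these libraries.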

Results

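Pol I occupancy was measured along the transcribed rDNA of budding yeast in WT cells and in cells lacking CDC73 or PAF1, which encode subunits of the Paf1 complex, a factor that travels with elongating RNA polymerases. The 35S precursor holds the 18S, 5.8S and 25S rRNAs, separated and flanked by spacers that are removed during processing: the 5' external transcribed spacer (5' ETS), internal transcribed spacers 1 and 2 (ITS1 and ITS2) and the 3' ETS. On chromosome XII of build R64 the 5' ETS lies at 466870 to 467569, 18S at 465070 to 466869, ITS1 at 464709 to 465069, 5.8S at 464551 to 464708, ITS2 at 464319 to 464550, 25S at 460923 to 464318 and the 3' ETS at 460712 to 460922. Each genotype had 2 libraries. The median position had 41 and 20 reads in the WT libraries, 1650 and 1275.5 in the cdc73 deletion libraries and, if the smallest value there is 1 read, 3021 and 1427 in the paf1 deletion libraries. The shallowest deletion library was thus 29.5 times deeper than the deepest WT library. Any batch or other difference that went with depth cannot be told apart from genotype in a comparison with WT. Read number alone was set equal by thinning, which drew 226202 reads per library in proportion to its values. The shallow WT libraries thus kept their own sampling noise and gained that of the draw. The Spearman rho across positions was then 0.912 between the WT libraries and on average 0.702 for WT and the paf1 deletion and 0.617 for WT and the cdc73 deletion. This argues against read number as the whole cause of the differing profiles.

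The first question was how loss of PAF1 changed Pol I occupancy. The 5' ETS held 9.41% ± 1.08 of occupancy in WT and 4.52% ± 0.0388 in the paf1 deletion (SD, n = 2 each), a 2.08-fold lower share. The share of ITS1 was 1.31% ± 0.0462 in WT and 0.962% ± 0.0229 in the deletion. The share of 5.8S was higher in the deletion, at 3.55% ± 0.288 against 1.80% ± 0.0482, and 25S held 59.0% ± 0.390 against 56.3% ± 0.695. The shares of ITS2 (1.06% ± 0.103 against 0.955% ± 0.0511) and of the 3' ETS (0.634% ± 0.0619 against 0.631% ± 0.0177) overlapped between the genotypes. The 18S share was 30.3% ± 0.0471 against 29.6% ± 0.220. Because shares add up to a fixed total, the lower 5' ETS share alone raises the others, so the small rises of 18S and 25S need not be gains. For the regions that did not overlap, the exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow.

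The change within the 5' ETS was uneven: of its 7 windows 5 were called lower and 1, the first, higher (log2 0.39). In the window from position 501 to 600 the share was 2.50% ± 0.432 in WT and 0.359% ± 0.0105 in the paf1 deletion, a log2 fold change of -2.79 (SE 0.09). The windows that end at positions 200 and 400 changed by -1.36 and -1.27. The last window, from position 6801 in the 3' ETS on, changed by -2.50, from 0.0629% ± 0.00164 to 0.0112% ± 0.00159, and window 2001 to 2100 in 18S by -1.05. The largest rises were in window 5401 to 5500 of 25S (log2 1.10), window 2901 to 3000 of 5.8S (0.93) and window 6101 to 6200 of 25S (0.89), followed by 3001 to 3100 (0.83) and 3201 to 3300 (0.75). Of 69 windows, limma called 29 higher and 24 lower. Taken as shares of the spacer total, which was itself lower in the deletion (7.17% ± 0.149 against 12.3% ± 0.963), 10 windows of the spacers were called higher and 4 lower, in an alternative chosen after seeing the data.

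At single positions, all 10 of the largest falls lay in the 5' ETS, most of them in the short stretch from position 527 to 539. Position 539 (chromosome XII 467031) had a signal of 1950 ± 361 in WT and 14.5 ± 3.08 in the paf1 deletion, a log2 fold change of -4.99 with an adjusted p of 1.77e-05 by limma. Position 537 fell from 1471 ± 102 to 42.1 ± 12.1, and position 366 from 1063 ± 57.5 to 54.6 ± 9.33. Among the 10 largest rises, 4 lay in 18S, 2 in 5.8S and 4 in 25S. Position 2497, 3 nt before the 3' end of 18S, rose from 102 ± 12.0 to 1139 ± 290 (log2 2.96), and position 3017, near the 3' end of 5.8S, from 282 ± 1.499 to 2131 ± 345 (log2 2.71). Near the same ends, position 2498 rose from 805 ± 208 to 5164 ± 727 and position 3015 from 424 ± 30.3 to 2620 ± 345. Mature and nascent RNA were not separated, so these rises near mature 3' ends need not reflect Pol I. Position 1063 in 18S rose from 231 ± 32.6 to 1654 ± 28.7. Over all 6839 positions tested, 2024 were called higher and 1341 lower, of which 501 and 519 changed at least 2-fold. With the medians of the libraries set equal, the split was 1534 higher and 1904 lower, and with all libraries thinned to one depth 926 and 752. The groups did not overlap at 75.9% of positions, where chance gives 33.3%.

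By region, 302 of 692 tested positions of the 5' ETS were called lower and 82 higher, and 97 of 156 positions of 5.8S higher and 4 lower. Adjusted over the list alone, the counts were 311 lower and 86 higher in the 5' ETS and 100 higher and 5 lower in 5.8S. In 25S 1226 of 3395 were higher and 592 lower, and in 18S 529 of 1798 were higher and 294 lower. ITS1 had 34 higher and 83 lower, ITS2 44 higher and 26 lower, and the 3' ETS 12 higher and 40 lower. With a preset correlation camera gave an adjusted p of 2.0e-11 for the 5' ETS and 6.1e-08 for 5.8S. With an estimated correlation the adjusted p was 0.190 and 0.245, and no region passed in any of the 3 comparisons. ITS2 had a median log2 change of 0.04 and a mean of 0.03 where camera pointed down, with an adjusted p of 0.798. In the authors' deposited table, 1482 of 6848 positions had an unadjusted p under 0.05, and 1 passed after Benjamini-Hochberg adjustment.

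**Figure D1:**
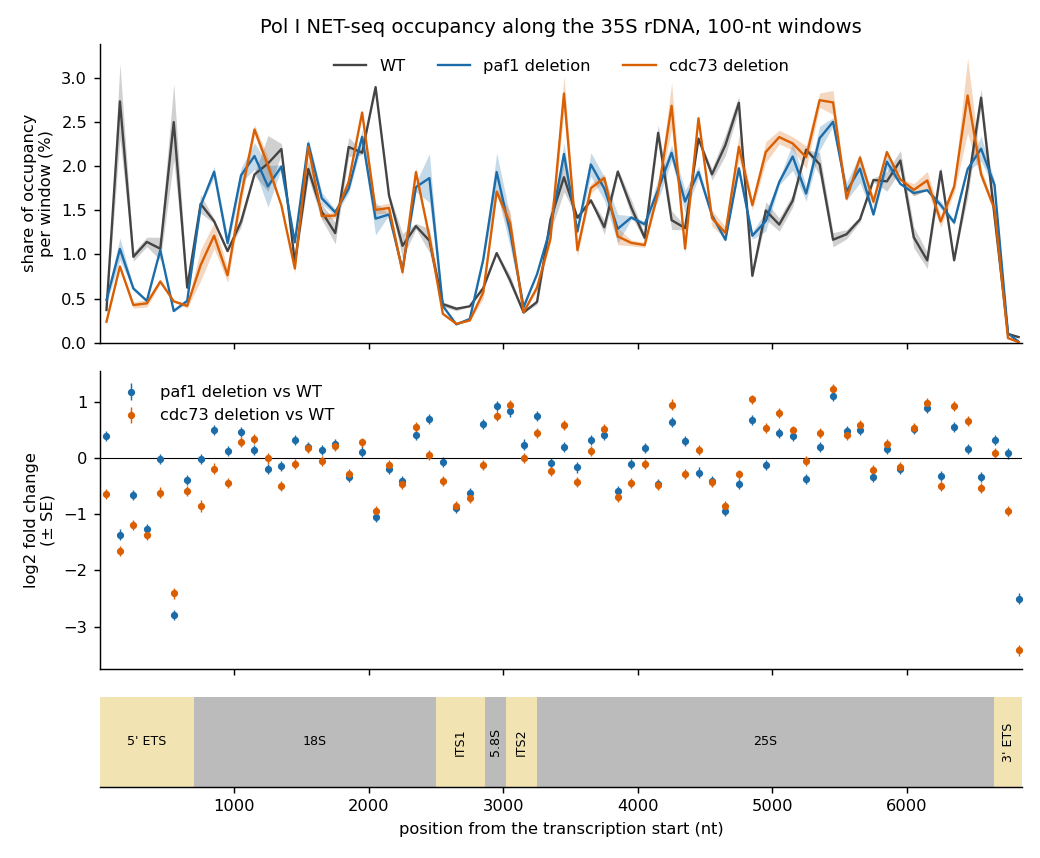
Share of occupancy per 100-nt window (percent, top; lines are means and bands the SD of 2 libraries) and log2 fold change against WT (middle; points with SE from limma), by position in nt from the start of the transcribed rDNA, with the regions below (spacers in yellow, mature rRNA in grey). Windows of the 5' ETS lie lowest from position 501 to 600, at log2 -2.79 in the paf1 deletion and -2.40 in the cdc73 deletion.

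**Figure D2:**
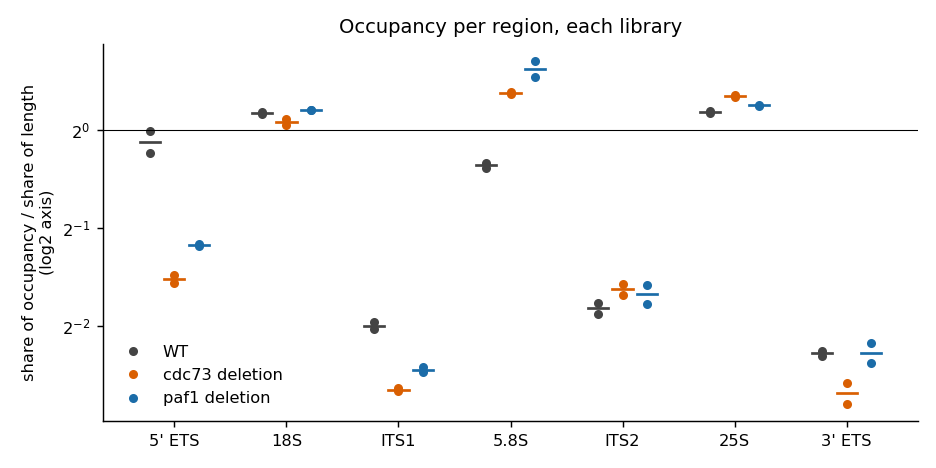
Share of occupancy divided by share of length for each region, on a log2 axis. Points are libraries and bars the mean of 2. In the 5' ETS the 4 deletion libraries lie below both WT libraries, and in 5.8S above them.

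The second comparison asked the same of CDC73. In the cdc73 deletion the 5' ETS held 3.55% ± 0.137 of occupancy, 2.65-fold less than the 9.41% ± 1.08 of WT, and 25S held 63.2% ± 0.603 against 56.3% ± 0.695. The share of 5.8S was 2.998% ± 0.0358 against 1.80% ± 0.0482. ITS1 held 0.834% ± 0.0109 against 1.31% ± 0.0462, the 3' ETS 0.477% ± 0.0501 against 0.631% ± 0.0177, 18S 27.8% ± 0.807 against 29.6% ± 0.220 and ITS2 1.09% ± 0.0633 against 0.955% ± 0.0511. With positions capped at the 99th percentile the 18S difference shrank from -1.77 to -0.841 percentage points. None of these shares overlapped between the genotypes, and each gave p = 0.333 in the exact permutation test.

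All 7 windows within the 5' ETS were called lower in the cdc73 deletion. The window 501 to 600 changed by log2 -2.40 (SE 0.10), from 2.50% ± 0.432 to 0.469% ± 0.0104, and the windows that end at positions 200, 300 and 400 by -1.65, -1.19 and -1.36. The last window, from position 6801 on, changed by -3.42, from 0.0629% ± 0.00164 to 0.00594% ± 0.00108. The largest rises were in 25S, in window 5401 to 5500 (1.22), 4801 to 4900 (1.04), 6101 to 6200 (0.98) and 4201 to 4300 (0.95), and in window 3001 to 3100 across 5.8S and ITS2 (0.94). Of 69 windows, 24 were called higher and 30 lower. As shares of the spacer total (5.96% ± 0.239 against 12.3% ± 0.963 of occupancy), 9 windows of the spacers were called higher and 4 lower.

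All 10 of the largest falls at single positions lay in the 5' ETS here too, most of them from position 529 to 539. Position 536 had a signal of 2012 ± 165 in WT and 6.68 ± 0.461 in the deletion, a log2 fold change of -5.33 with an adjusted p of 4.22e-05 by limma. Position 163 fell from 2257 ± 63.5 to 23.3 ± 0.114 and position 187 from 1261 ± 12.6 to 21.3 ± 1.49. Of the 10 largest rises, 8 lay in 25S and 2 in 18S. Position 4968 rose from 181 ± 44.2 to 2253 ± 94.99 (log2 3.36), position 4273 from 226 ± 55.2 to 2490 ± 350 and position 5046 from 428 ± 7.77 to 3918 ± 356. In total 2054 of 6839 positions were called higher and 2011 lower, of which 723 and 776 changed at least 2-fold, and the groups did not overlap at 81.2% of positions, where chance gives 33.3%. On the recovered reads, edgeR called 2272 higher and 2050 lower, and after thinning to one depth limma called 1275 and 1277.

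By region, 368 of 691 positions of the 5' ETS were lower and 94 higher, and 71 of 156 positions of 5.8S were higher and 23 lower. Adjusted over the list alone, these counts were 375 and 95, and 71 and 23. ITS1 had 53 higher and 120 lower, ITS2 70 higher and 61 lower, the 3' ETS 15 higher and 59 lower, 18S 511 higher and 546 lower and 25S 1240 higher and 834 lower. Camera gave the 5' ETS an adjusted p of 2.5e-09 at the preset correlation and an adjusted p of 0.159 with an estimated correlation. In the authors' deposited table, 1854 of 6846 positions had an unadjusted p under 0.05 and none passed the adjustment, with a smallest adjusted value of 0.0939.

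The third comparison set the deletions against each other. The paf1 deletion held more occupancy in the 5' ETS (4.52% ± 0.0388 against 3.55% ± 0.137), 18S (30.3% ± 0.0471 against 27.8% ± 0.807), ITS1 (0.962% ± 0.0229 against 0.834% ± 0.0109), 5.8S (3.55% ± 0.288 against 2.998% ± 0.0358) and the 3' ETS (0.634% ± 0.0619 against 0.477% ± 0.0501), and less in 25S (59.0% ± 0.390 against 63.2% ± 0.603). Each difference had an exact permutation p of 0.333. With positions capped at the 99th percentile the difference shrank from 0.157 to 0.0529 percentage points in the 3' ETS, from 2.47 to 1.51 in 18S and from -4.23 to -2.87 in 25S. ITS2 overlapped. The depths of these 4 libraries overlapped.

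Single positions of the 5' ETS differed strongly and in both directions. Position 405 had a signal of 1073 ± 138 in the paf1 deletion and 11.01 ± 1.77 in the cdc73 deletion (log2 4.26, adjusted p 1.78e-06 by limma), position 622 had 714 ± 8.20 and 31.9 ± 2.99, and position 163 had 640 ± 160 and 23.3 ± 0.114. In the other direction, position 108 had 26.1 ± 2.41 and 547 ± 40.2, and position 631 had 30.98 ± 2.90 and 530 ± 0.553. Of the 10 positions most in favour of the paf1 deletion 9 were purines, and of the 10 most in favour of the cdc73 deletion 8 were pyrimidines. Position 6411 in 25S had 339 ± 260 and 7305 ± 3654 (log2 -4.34), with a wide spread between libraries. In total 2357 of 6846 positions were higher in the paf1 deletion and 1407 lower, of which 293 and 173 changed at least 2-fold. With the medians set equal the split was 1563 higher and 2226 lower, and with all libraries thinned to one depth only 415 were higher and 310 lower. The groups did not overlap at 79.8% of positions, where chance gives 33.3%.

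In windows, the paf1 deletion was higher in 24 of 69 and lower in 12. As shares of the spacer total, 6 windows of the spacers were higher and 4 lower. The largest differences were in the first window, 1 to 100 (log2 1.03), in 6701 to 6800 (1.02), the last window (0.92), 701 to 800 (0.84) and 2801 to 2900 (0.73), and in the other direction in 4901 to 5000 (-0.65), 6401 to 6500 (-0.50), 3401 to 3500 (-0.40), 4401 to 4500 (-0.40) and 501 to 600 (-0.39). These counts rested on single libraries: 8 windows were called without cdc73 deletion replicate 2, 22 without paf1 deletion replicate 1 and 2 without paf1 deletion replicate 2. By region, 337 of 697 positions of the 5' ETS were higher and 197 lower, 67 of 156 in 5.8S were higher and 5 lower, and camera gave 5.8S an adjusted p of 0.0246 at the preset correlation and an adjusted p of 0.865 with an estimated correlation. In the other regions 717 were higher and 363 lower in 18S, 169 and 85 in ITS1, 92 and 59 in ITS2, 914 and 666 in 25S and 61 and 32 in the 3' ETS. Camera pointed down for 25S (adjusted p 0.211) and ITS2 (adjusted p 0.921), where medians and means were above 0. In the authors' deposited table, 1538 of 6848 positions had an unadjusted p under 0.05 and 3 passed the adjustment.

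The mean position of occupancy moved toward the 3' end in both deletions, from 3471 ± 43.1 nt in WT to 3658 ± 8.56 in the paf1 deletion and 3827 ± 19.5 in the cdc73 deletion. The spacers, 21.9% of the length, held 12.3% of occupancy in WT, 7.17% in the paf1 deletion and 5.96% in the cdc73 deletion. Relative to length, ITS1 stood at 0.243 and 0.256 in the WT libraries, against 1.12 and 1.13 in 18S and 1.13 and 1.15 in 25S. The 5' ETS stood at 0.997 and 0.847 there. How much of the 18S and 25S signal was mature rRNA was not measured, so changes in these stretches need not reflect Pol I. Because mature and nascent RNA were not separated, the mean position does not tell a shift of Pol I from a change in mature RNA. Occupancy was most even in the paf1 deletion, with a Gini coefficient of 0.509 ± 0.00386 against 0.556 ± 0.00361 in WT and 0.565 ± 0.0108 in the cdc73 deletion, and the last 2 overlapped. The top 1% of positions held 8.85% ± 0.0440 in the paf1 deletion, 10.4% ± 0.484 in WT and 11.5% ± 0.476 in the cdc73 deletion. The excess of the cdc73 deletion over WT turned to -0.115 percentage points with positions capped at the 99th percentile. That cap sets these same top positions to a single value in each library, so it does not test the excess. Signal within 2 nt of the mature rRNA 3' ends, where mature and nascent RNA were not separated, made up 0.460% ± 0.0690 in WT, 0.883% ± 0.112 in the cdc73 deletion and 1.28% ± 0.0202 in the paf1 deletion. With 10 nt on each side the gaps to WT were 1.06 and 1.53 percentage points. The non-overlapping comparisons had an exact permutation p of 0.333.

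Profiles were most alike within a genotype, with a Spearman rho across positions of 0.954 in WT, 0.991 in the cdc73 deletion and 0.977 in the paf1 deletion (Pearson r of log2 values 0.961, 0.991 and 0.980). Between genotypes the mean rho was 0.831 for the 2 deletions, 0.733 for WT and the paf1 deletion and 0.644 for WT and the cdc73 deletion (Pearson r 0.838, 0.705 and 0.611). In 100-nt windows the order of the pairs with WT turned, at 0.544 for the paf1 deletion and 0.5615 for the cdc73 deletion. The fold changes of the deletions against the same WT libraries had an r of 0.779 across positions and a covariance of 0.515. In 100 simulations of unchanged deletions against those WT libraries, the mean r was 0.740, the largest r 0.767 and the mean covariance 0.0204. With a different WT library for each deletion r was 0.711 and 0.740. Both deletions called 1347 positions higher, where independent lists would share 608, and 1104 lower, where they would share 394, and part of that excess may come from the shared WT libraries.

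Occupancy by the base at the RNA 3' end set the cdc73 deletion apart from the other genotypes for A, C and U, but not for G. In the spacers, positions with A had a relative occupancy of 1.33 ± 0.0128 in WT, 1.23 ± 0.00500 in the paf1 deletion and 0.566 ± 0.0145 in the cdc73 deletion (SD, n = 2 each, where 1 is the mean over positions). In the same order, positions with U had 0.733 ± 0.0403, 0.730 ± 0.0293 and 1.21 ± 0.0160, with C 0.949 ± 0.0207, 0.878 ± 0.0269 and 1.18 ± 0.0166 and with G 1.02 ± 0.0280, 1.18 ± 0.0543 and 1.11 ± 0.0165. Over all positions A had 1.15 ± 0.00761, 1.22 ± 0.000726 and 0.992 ± 0.00450, and U 0.878 ± 0.0109, 0.886 ± 0.00610 and 1.04 ± 0.00330. The spacers alone, chosen after seeing the data, thus turned the A difference of the paf1 deletion from WT from 0.0784 to -0.0917 and the G differences of both deletions from WT above 0. At the next template position, over all positions, C had 0.998 ± 0.0133 in WT, 0.769 ± 0.000418 in the paf1 deletion and 0.903 ± 0.0133 in the cdc73 deletion, and U 0.964 ± 0.000968, 1.00 ± 0.00776 and 0.831 ± 0.000440. In the spacers the next-position C of the cdc73 deletion (0.963 ± 0.00135) overlapped that of WT (0.965 ± 0.0575).

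**Figure D3:**
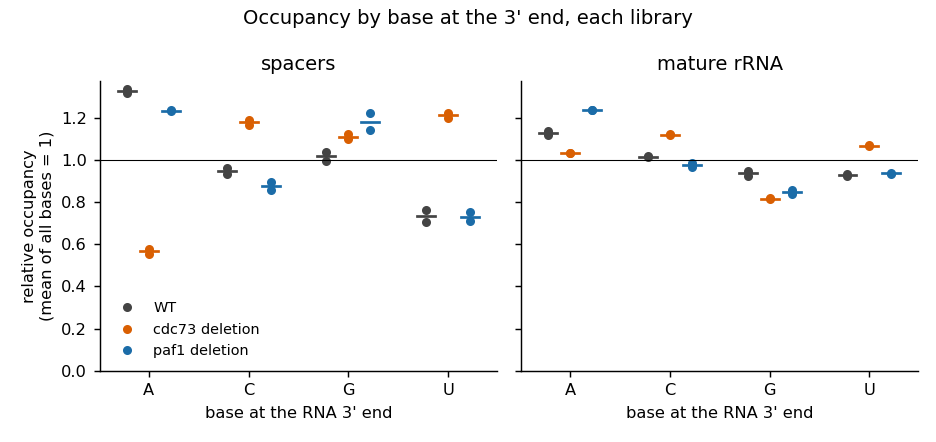
Relative occupancy by base at the RNA 3' end (mean of all bases = 1) in the spacers (left) and the mature rRNA stretches (right). Points are libraries and bars the mean of 2. In the spacers, A stands at 0.566 in the cdc73 deletion and at 1.33 in WT.

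The rule for pause sites named 130 positions in WT, 135 in the cdc73 deletion and 114 in the paf1 deletion. The deletions shared 55 of them, where independent lists would share 2.24. WT shared 28 with the paf1 deletion and 17 with the cdc73 deletion, where independent lists would share 2.16 and 2.56. In the mature rRNA stretches the deletions shared 48 sites, against 21 and 13. In the spacers the counts depended on the rule: at the same position the deletions shared 7 sites, against 7 and 4, and within 1 nt they shared 15, against 7 and 7. Of the sites, 66.9% were purines in WT, 64.04% in the paf1 deletion and 41.5% in the cdc73 deletion. Simulated profiles without planted sites gave 44, 63 and 55 sites at those depths, so a part of each list can arise without any pause.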

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

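Thinning, edgeR, array weights, the spacers alone and the crossed pairing were chosen after seeing the data. Values are listed for the paf1 deletion against WT, the cdc73 deletion against WT and the paf1 deletion against the cdc73 deletion, in this order. With the upper 0.5 of positions by mean alone, 2155, 2530 and 1768 were called, where fewer were tested. With all libraries thinned to 226202 reads 1678, 2552 and 725 were called, where fewer reads were left and the draw added noise. Leaving out 1 library gave 2384 to 4216, 2960 to 5122 and 2669 to 3921 called positions, with a lone library assumed to vary like the others. With the replicate number as a replicate block, 3482, 4277 and 3551 positions were called and no count moved by over 1.5 times. The deviations of libraries that share a number correlated at 0.114, 0.0338 and -0.227, which gives no sign that the numbers pair the libraries. Pairing is not excluded, since sampling noise in the shallow WT libraries would weaken the correlations with WT. A crossed pairing of the deletions called 4256 positions. Leaving out 1 library gave calls in 53.6 to 68.1, 71 to 75.4 and 2.90 to 39.1 percent of windows, all below the 76.8, 78.3 and 52.2 percent with every library. The 60 named positions passed in all 918 checks and none changed direction, and the 30 named windows lost their call in 16 of 240. Both sets were picked as the largest changes in these same libraries, so this outcome was largely set by the choice and is no independent support. The depth of WT limits how small a change can be called in the comparisons with WT. The cause of the changes below was not tested.

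With positions capped at the 99th percentile the differences were 5' ETS share 0.736 (paf1 to cdc73), 18S share -0.841 and 1.51 (cdc73 to WT and paf1 to cdc73), 5.8S share 1.39 and 0.874 (paf1 to WT and cdc73 to WT). They were 25S share 5.62 and -2.87 (cdc73 to WT and paf1 to cdc73), 3' ETS share -0.115 and 0.0529 (paf1 to WT and paf1 to cdc73), mean position (nt) 290 and -118 (cdc73 to WT and paf1 to cdc73). They were top 1% share -0.115 and -1.36 (cdc73 to WT and paf1 to cdc73), 3' A 0.113, -0.105 and 0.218, 3' C -0.0704, 0.0679 and -0.138. They were 3' G -0.0853 (cdc73 to WT), 3' U -0.00967, 0.136 and -0.146, next A 0.125 (cdc73 to WT). They were next C -0.134 and -0.0945 (cdc73 to WT and paf1 to cdc73), next G 0.000881 (paf1 to WT), next U 0.0342, -0.124 and 0.159. With the mature 3' ends left out the differences were 18S share 0.515 (paf1 to WT), 5.8S share 1.11 (cdc73 to WT), Gini coefficient -0.0514 (paf1 to WT). They were top 1% share -2.31 and -3.08 (paf1 to WT and paf1 to cdc73). Divided by the local mean the differences were 3' A 0.0662, -0.254 and 0.320, 3' C -0.0535, 0.0881 and -0.142, 3' G -0.00796 and -0.0405 (paf1 to WT and cdc73 to WT). They were 3' U -0.0206, 0.224 and -0.244, next A 0.0824 and -0.0316 (paf1 to WT and paf1 to cdc73), next C -0.262, -0.142 and -0.120. They were next G 0.0503, 0.198 and -0.148, next U 0.0482, -0.201 and 0.249. In the spacers alone the differences were 3' A -0.0917, -0.760 and 0.668, 3' C -0.0710, 0.229 and -0.300, 3' G 0.166, 0.0946 and 0.0711. They were 3' U -0.00262, 0.479 and -0.481, next A 0.0255, 0.135 and -0.109, next C -0.345, -0.00182 and -0.343. They were next G 0.0294, 0.393 and -0.363, next U 0.120, -0.388 and 0.508. The 3' ends widened to 10 nt gave 1.53 and 1.06 percentage points above WT.

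Profile correlations of WT with the cdc73 deletion, of WT with the paf1 deletion and between the deletions were 0.382, 0.470 and 0.741 on linear values, 0.561, 0.544 and 0.880 in 100-nt windows and 0.617, 0.702 and 0.796 after thinning. The similarity of fold changes was 0.711 and 0.740 with a different WT library for each deletion and 0.886 in windows. Pause sites in WT, the cdc73 deletion and the paf1 deletion numbered 250, 270 and 221 at mean + 2 SD and 77, 75 and 66 at mean + 4 SD. Sites shared by the same pairs as above numbered 49, 71 and 118 at mean + 2 SD and 9, 15 and 33 at mean + 4 SD.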

Other observations

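All tests were chosen after the data had been seen. Only the bound of the thinning test was written before any thinned value was seen, when the correlations without thinning were known. Which genotypes resembled each other changed along the transcript. In 25S the mean rho across positions was 0.846 between the deletions, 0.625 between WT and the paf1 deletion and 0.544 between WT and the cdc73 deletion. In ITS1 these values were 0.597, 0.724 and 0.562, and in ITS2 0.497, 0.669 and 0.360. In the 5' ETS they were 0.523, 0.669 and 0.532, but in the 3' ETS 0.705, 0.694 and 0.496, with library pairs that overlapped between the first and the second. In 18S they were 0.750, 0.714 and 0.583 and in 5.8S 0.894, 0.849 and 0.758. Signal past the scaling sum made up 0.1104% ± 0.00519 of occupancy in WT, 0.0406% ± 0.000608 in the paf1 deletion and 0.0201% ± 0.00121 in the cdc73 deletion.

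In the spacers, 256 of 422 tested positions with A were called lower in the cdc73 deletion than in WT and 17 higher, while 133 of 495 with U were lower and 117 higher. With C, 92 of 232 were lower and 45 higher, and with G, 127 of 341 were lower and 53 higher. Positions that follow a G had a relative occupancy of 1.49 ± 0.0215 in WT, 1.40 ± 0.0363 in the paf1 deletion and 1.29 ± 0.0211 in the cdc73 deletion. The log2 ratio of occupancy at purines over pyrimidines in the 3' ETS was -0.57 ± 0.18 in WT, -2.03 ± 0.07 in the paf1 deletion and -2.19 ± 0.09 in the cdc73 deletion, the one spacer in which the paf1 deletion lay far below WT.

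The lower 5' ETS share of both deletions was weighed first. If more mature rRNA had only diluted the nascent RNA, all spacers would have fallen by one factor, but the log2 folds of the 3' ETS and ITS1 lay above that of the 5' ETS by at least 0.60 in both deletions, more than 3 times the SE. The signal past the scaling sum relative to the first part of the 3' ETS was also lower in the deletions, by a log2 ratio of -1.95. The spacers thus did not fall by a common factor. However, the 3' ETS starts directly after 25S and ITS1 directly after 18S, and signal at both mature 3' ends was higher in the deletions. At the 18S 3' end it was 0.0958% of occupancy in WT, 0.539% in the paf1 deletion and 0.269% in the cdc73 deletion. Signal that runs past a mature end would raise the folds of these spacers and lower that ratio. These spacer folds therefore do not decide whether dilution was the whole cause. Within the 5' ETS, which holds no mature rRNA, dilution alone would change all windows by the same factor. In the paf1 deletion the log2 change was 0.39 at positions 1 to 100, -0.02 at 401 to 500 and -2.79 at 501 to 600 (SE 0.09). In the cdc73 deletion it was -0.64 at 1 to 100 (SE 0.09) and -2.40 at 501 to 600 (SE 0.10). These values argue against dilution as the whole cause. Its part in the lower share was not tested. The deletion libraries were at least 29.5 times deeper than the WT libraries. An effect of library batch, or of anything else that went with depth, cannot be told apart from that of the genotype. After thinning, the rho across the 5' ETS was 0.900 between the WT libraries and on average 0.602 for WT and the paf1 deletion and 0.462 for WT and the cdc73 deletion. This argues against read number as the whole cause of the differing 5' ETS profiles, but the 5' ETS share was not compared after thinning.

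The deletion profiles were more alike than either was to WT. With all libraries thinned to one depth, the mean rho between the deletions still lay 0.0942 above the higher of the WT values, beyond the margin of 0.03. The draw added noise to WT libraries that already had their own, which favours such a gap, so the margin alone does not decide. However, the thinned WT libraries, which both carried that noise, had a rho of 0.912, against 0.702 for WT and the paf1 deletion. This argues against counting noise as the whole cause of the low WT values. The likeness did not run along the whole transcript, since in the 5' ETS the rho between the deletions (0.495 to 0.552) lay below that of WT and the paf1 deletion (0.627 to 0.715), by a difference in means of -0.146. In 18S the library pairs overlapped (0.716 at the lowest between the deletions, 0.742 at the highest between WT and the paf1 deletion), but over all mature rRNA stretches together the deletions were more alike than WT and the paf1 deletion (0.783 to 0.839 against 0.624 to 0.689), and over all spacers together less alike than that pair (0.640 to 0.664 against 0.712 to 0.773) but more than WT and the cdc73 deletion (0.579 to 0.622, a gap that closed to an overlap after thinning). What made the mature stretches alike was not tested.

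The cdc73 deletion had fewer purines at the 3' end, which in the spacers was a fall of A (0.566 against 1.33 in WT), while G was higher (1.11 against 1.02). A ligation bias that depended on the last base alone would give a similar shift everywhere. However, the shift of the log2 purine to pyrimidine ratio from WT was -1.13 in the spacers and -0.34 in the mature rRNA stretches. The difference was -0.80 (SE 0.05). A bias that depends on more of the RNA than its last base was not tested and stays open. With positions capped at the 99th percentile the spacer shift was -1.03 (SE 0.04), which argues against a few very high positions. No biological explanation of the shift was tested.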
